A study of Castanea mollissima with 2 samples.

How the data were processed

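RNA sequencing had been carried out on catkins, the flower-bearing spikes of chestnut, from 2 cultivars of Chinese chestnut (Castanea mollissima). The labels describe 1 library from Yanshanhong as normal catkins and 1 library from Heishanzhai7 as shorter catkins of a mutant. They are called the normal and the mutant library here. Each group held 1 library, so there was no spread between replicates, and the catkin phenotype and the cultivar differed together. The extraction protocol in the labels speaks of berries, whereas the tissue label of both libraries is catkins, and the genotype label is the same word, recessive, for both.

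Each library had 1 deposited table with 92000 gene entries, in the same order and with the same transcript identifiers in both. Per the submitters' processing notes, HISAT, an aligner, and RSEM, a program that estimates read counts per transcript, were used. Their versions, their roles and the reference they were run against are not given in the sources used here. Per the file headers, the deposited values are expected counts (reads estimated per gene entry, not normalized), TPM (transcript abundance scaled to the same sum in each library) and FPKM (fragments relative to effective length and library total). The deposited TPM values summed to 999998 in the normal and 1000000 in the mutant library. The deposited expected counts are given to 2 decimals. Of those above 0, 88.25% were exactly whole at that precision in the normal and 89.3% in the mutant library, and 28964 and 12454 entries were at 0. The rest carry fractions, as reads shared between entries are divided by estimation, so that counts of near-identical entries are uncertain. The deposited tables also give a length and an effective length per entry, and the gap between them was 77.86 bases in the normal and 84.37 bases in the mutant library.

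The identifiers have the form of a component number and a subgraph number, and the tables pair them with no gene name, description or sequence. No reference genome or annotation was used here. The 36 gene lists fixed before the data were examined (hormone pathways, programmed cell death, floral regulators, anther and pollen genes, cell wall enzymes, markers of other tissues and others) could therefore not be matched to entries, and no list or pathway result is given. For the same reason, no position in a genome is given.

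Expected counts were rounded to whole numbers. Rounded totals were 23089247 counts in the normal and 19624934 in the mutant library. Counts were scaled by the trimmed mean of M values (TMM) with edgeR 4.0.16 in R 4.3.3, with factors of 0.9243 for the normal and 1.0819 for the mutant library. For the 25994 entries with at least 20 counts over both libraries, the ratio of mutant to normal was taken on the log2 scale with a pseudocount of 0.5 counts, and a 95% exact conditional (Clopper-Pearson) interval was computed from the 2 counts. An entry was counted as higher or lower in the mutant library where the ratio was at least 2-fold and this interval excluded equality. The intervals cover counting error of these 2 libraries only, treat estimated counts as independent reads, and say nothing about variation between trees or catkins. No p-value was computed. A count of 0 allows up to 3 counts, which is 0.13 CPM (counts relative to the library total) in the normal and 0.153 in the mutant library. Where an entry was at 0 in 1 library, its fold was set against these 3 counts of that library and is a lower bound under that allowance. The 95% interval above reaches to smaller folds for such entries.

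Classes of entries were described by their median log2 ratio and by its place among the medians of 10000 random lists of the same size, matched on mean abundance in 20 bins. Mean abundance was taken from scaled counts, without a correction for length. Correlations between the libraries were taken across entries on log2(CPM + 0.5). The rule for naming entries, set before the data were examined, took those with the highest and lowest log2 ratios among entries with at least 200 counts over both libraries, limited to 2 identifiers in each direction because the entries have no names. The most abundant entries are described by rank and length.

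The ratio and interval procedure was tested on simulated data. Counts of the real entries were drawn from a Poisson distribution at the real library totals, and 200 entries were changed. In this simulated comparison of mutant against normal, 26325 entries were tested. Of the entries changed 3-fold, 59 of 60 were recovered, of those changed 4-fold, 60 of 60, and of those changed 8-fold, 80 of 80. The changed entries were drawn only from those whose Poisson means summed to at least 100 counts over both libraries. These shares therefore do not cover entries of fewer counts. In the real data 9221 of the entries had 20 to 99 counts over both libraries, and 3226 of these were called higher. Recovery at such counts was not tested. Of 26125 unchanged entries, 229 (0.877%) were called, and the interval covered equality in 95.9%. Unchanged entries were drawn from the counting model that the interval assumes, so this coverage followed from the setting. The share called is no estimate of false calls in the real libraries.

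The alternatives were scaling by the total count, DESeq2 1.42.0 median-of-ratios size factors, the deposited FPKM values as log2(FPKM + 1), a pseudocount of 5 counts, no filter on low counts, a minimum of 100 counts, a 4-fold threshold, and thinning of the normal library to the total of the mutant library. A fit without the 2 most abundant entries, and a count without entries at 0 in either library, were chosen after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.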

Results

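The transcriptome of chestnut catkins was measured in 1 library of normal catkins (cultivar Yanshanhong) and 1 library of the shorter catkins of a mutant (cultivar Heishanzhai7), a comparison meant to address the mutation that shortens the catkin. The normal library held 23089247 counts and the mutant library 19624934, over 92000 gene entries with a median length of 360 bases. The entries carry identifiers without gene names, so the groups below are formed by abundance, length and number of transcripts. With 1 library per group there was no replicate error, and the intervals given reflect counting error only. The libraries also differed in cultivar, and the contribution of cultivar cannot be told apart from that of catkin type.

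Of the 25994 entries with at least 20 counts, 5669 (21.8%) were at least 2-fold higher in the mutant library and 3829 (14.7%) at least 2-fold lower, with counting intervals that excluded equality. The remaining 16496 were in neither class. The entries higher in the mutant library were mostly rare in normal catkins, with a median of 0.57 TPM there and 5.93 TPM in the mutant library. The entries lower in the mutant library were more abundant, with medians of 11.05 TPM in the normal and 2.99 TPM in the mutant library. The lower entries held 30.01% of all counts in the normal library and 11.28% in the mutant library, whereas the higher entries held 4.17% and 15.24%. In the lower set, 2 entries alone held 11.5% of all counts in the normal and 5.02% in the mutant library. Both sets were chosen by the ratio, so part of these contrasts follows from that choice. Scaling by the total count moved the median log2 ratio of all 25994 entries by 0.23, from 0.05 to 0.28, and the split from 59.7% higher to 69.96% higher, with 6919 higher and 2971 lower.

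**Figure D1:**
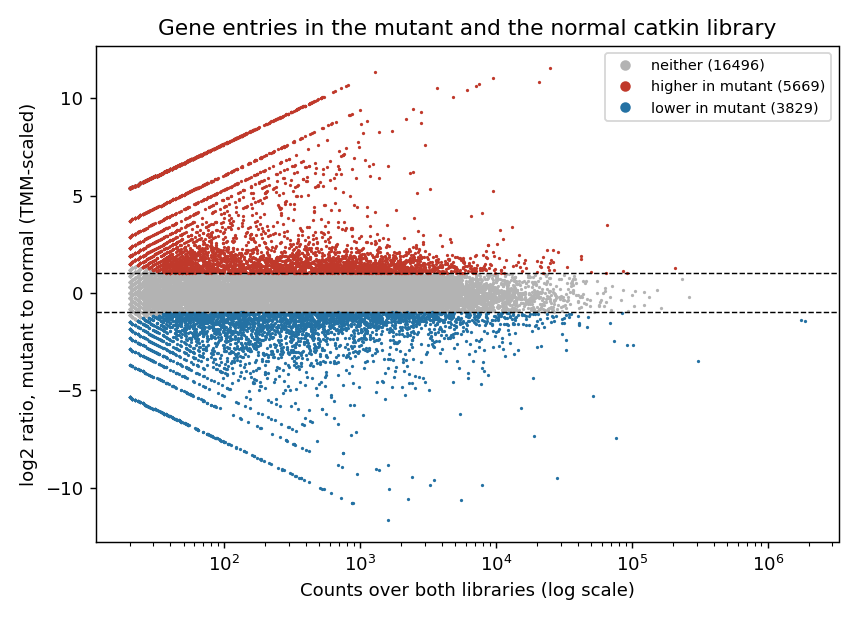
Log2 ratio of mutant to normal (vertical axis, TMM-scaled counts with a pseudocount of 0.5) against the counts over both libraries (horizontal axis, log scale) for 25994 gene entries, 1 point each. Red points are the 5669 entries higher and blue points the 3829 entries lower in the mutant library, dashed lines mark 2-fold, and the outermost oblique rows are entries at 0 counts in 1 library.

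The most abundant transcripts of the catkins took a smaller part of the mutant library. The same 2 entries ranked first and second in both libraries. They have lengths of 2467 and 3856 bases and identifiers of a single component, and together they took 11.5% of the counts in the normal library (Wilson 95% interval 11.484 to 11.51%) and 5.02% in the mutant library (5.008 to 5.027%). Their abundance was 33236 and 19654 TPM in the normal library and 14625 and 8856 TPM in the mutant library. On TMM-scaled counts the first was 2.71-fold and the second 2.65-fold lower in the mutant library. The next entry of the normal library, of 725 bases, was 11.34-fold lower in the mutant library, with 25356 TPM in the normal and 2689 TPM in the mutant library. The next entry of the mutant library, of 1503 bases, was 2.44-fold higher there, with 2462 TPM in the normal and 7199 TPM in the mutant library. An entry of 7592 bases, also among the 5 most abundant of both libraries, had 1090 TPM in the normal and 1108 TPM in the mutant library, and was 1.17-fold lower in the mutant library on TMM-scaled counts.

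**Figure D2:**
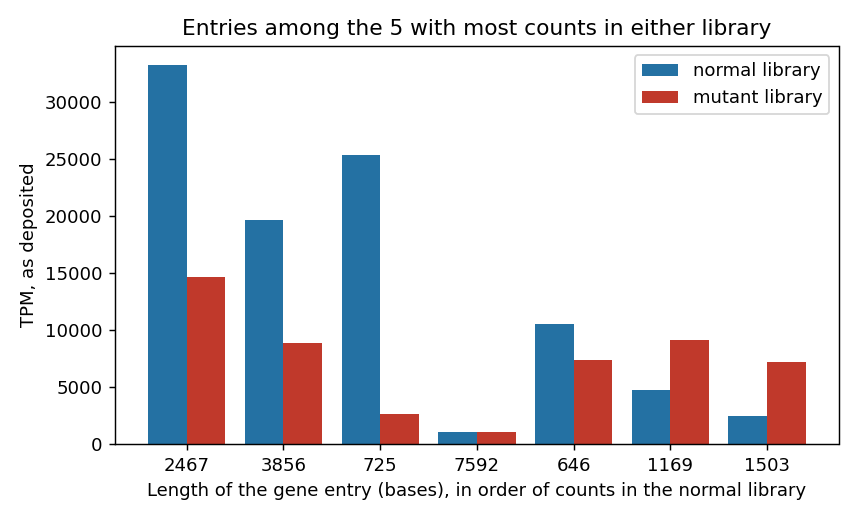
Deposited TPM (vertical axis, from 0) of the entries among the 5 with most counts in the normal (blue) or the mutant library (red), with 1 library per group and no error bars. The entries are labelled by their length in bases, and the entry of 725 bases shows the widest gap, from 25356 TPM in the normal to 2689 TPM in the mutant library.

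Lists of the most abundant entries overlapped in part. The 5 most abundant entries of each library shared 3, the top 100 shared 56 and the top 1000 shared 728. Among the top 100 of the mutant library, 24 entries were higher and 5 lower in that library by the 2-fold criterion. Among the top 100 of the normal library, 37 were lower in the mutant library and 4 higher. Each list was chosen for high counts in its own library, so some lean towards that library follows from the choice. Across the entries with at least 20 counts, the libraries correlated with a Pearson r of 0.872 and a Spearman rho of 0.841. Entries are not independent replicates, and no p-value was attached.

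A set of transcripts was counted in the mutant catkins and not at all in the normal ones. There were 1520 entries with at least 20 counts in the mutant library and 0 in the normal library, against 243 in the opposite direction. They made up 0.48% of the mutant library and 0.1% of the normal library. Their median lengths were 793 and 669 bases, and their highest counts were 1282 and 1588. The entries named by the rule, which ranks log2 ratios with a pseudocount of 0.5, were c56248.graph_c0 and c56246.graph_c0, higher in the mutant library, and c56640.graph_c0 and c39683.graph_c0, lower in it. The rank of the 3 of these that were at 0 in 1 library is set by the pseudocount: with a pseudocount of 5, the log2 ratio of c56246.graph_c0 went from 11.33 to 8.01, that of c56640.graph_c0 from -11.63 to -8.31 and that of c39683.graph_c0 from -10.77 to -7.46. Entry c56248.graph_c0 (870 bases) had 24770 counts, or 2186 TPM, in the mutant library and 8 counts, or 0.58 TPM, in the normal library, a ratio of 3112 with a counting interval of 1579 to 7209. Entry c56246.graph_c0 (224 bases) had 1282 counts in the mutant library and 0 in the normal library. It was at least 430-fold higher where the 0 is taken as up to 3 counts, as for the entries below. Entry c56640.graph_c0 (789 bases) had 1588 counts in the normal library and 0 in the mutant library, at least 527-fold lower. Entry c39683.graph_c0 (1224 bases) had 877 counts in the normal library and 0 in the mutant library, at least 291-fold lower.

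More of the gene entries were seen in the mutant catkins, although that library was the shallower one. A count of at least 1 was found for 79546 entries in the mutant library and 63036 in the normal library. Both libraries detected 50587 entries, the mutant library alone 28959 and the normal library alone 12449. Nearly all entries seen in a single library were rare: 94.8% of those in the mutant library alone and 98.0% of those in the normal library alone had under 20 counts, so presence in 1 library is poorly resolved for them at this depth.

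The balance of higher and lower entries changed with abundance. Among the 9221 entries with 20 to under 100 counts over both libraries, 35.0% were higher and 16% lower in the mutant library, with a median log2 ratio of 0.37. Among the 9363 entries with 100 to under 1000 counts, 18.1% were higher and 16.2% lower. Among the 6768 entries with 1000 to under 10000 counts, 10.3% were higher and 10.8% lower, with a median of -0.07 that turned to 0.16 under total-count scaling and to 0.15 with FPKM. Among the 628 entries with 10000 to under 100000 counts, 7.3% were higher and 17.0% lower, with a median of -0.24. That last median was -0.01 under total-count scaling and 0.00 with FPKM. The order of these 4 abundance classes was the same under total-count and median-of-ratios scaling and with FPKM.

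The longest entries had the highest median of the length classes, and the medians without adjustment for abundance did not rise steadily with length. The 4663 entries of at least 2000 bases had a median log2 ratio of 0.27, above those of all 10000 random lists matched on abundance, which ran from -0.10 to -0.02. In this class 17.5% were higher and 6.0% lower, both the smallest shares of the 4 classes. The 10128 entries of 1000 to under 2000 bases had a median of -0.05 (matched lists -0.02 to 0.04), with 18.7% higher and 14.4% lower. The 8144 entries of 500 to under 1000 bases had a median of 0.06 (matched lists 0.11 to 0.22), with 28.4% higher and 17.7% lower. The 3059 entries of under 500 bases had a median of -0.09 (matched lists 0.14 to 0.37), with 21.3% higher and 21.2% lower. Set against the middle of their matched lists, the medians of the classes from shortest to longest differed by -0.35, -0.11, -0.06 and 0.33, and so rose with length. All 4 medians lay outside the range of their lists, the shortest class about as far from the middle as the longest. Under total-count scaling the class medians from shortest to longest were 0.14, 0.28, 0.18 and 0.50, so those of the shortest class and of 1000 to under 2000 bases changed sign relative to 0, while the longest class remained the highest. Entries with 2 or more transcripts (8525 entries, median 0.15) lay above their matched lists (-0.03 to 0.05), and those with 1 transcript (17469 entries, median 0.01) lay below theirs (0.05 to 0.10). All these lists were matched on counts and not on length, so the part of length in this last difference was not tested.

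**Figure D3:**
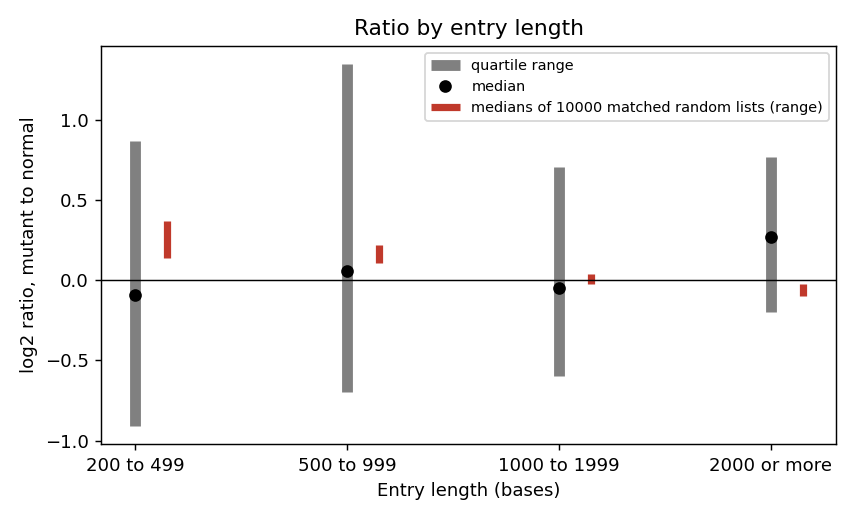
Log2 ratio of mutant to normal (vertical axis, TMM-scaled counts) by entry length in bases (horizontal axis). Black points are medians and grey bars quartile ranges over the entries of a class, red bars span the medians of 10000 random lists matched on abundance, and the class of 2000 bases or more has a median of 0.27 against -0.10 to -0.02 for its lists (under total-count scaling the class medians shift up, and those of the shortest class and of 1000 to under 2000 bases change sign, to 0.14 and 0.18).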

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

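More entries were higher than lower in the mutant library under every alternative run, but by how much depended on the filter, the threshold and the scaling. The share higher among the entries called was 59.7% in the main run, 69.96% with total-count scaling and 69.58% with FPKM. With a minimum of 100 counts, 2443 entries were higher and 2354 lower, or 50.9% higher, because the excess lay among entries of few counts. With no filter on low counts, 12589 were higher and 5559 lower. At a 4-fold threshold there were 3104 and 1608. With log2(FPKM + 1), 5313 were higher and 2323 lower. FPKM is relative to the library total and not TMM-scaled, and total-count scaling alone gave 2971 lower, against 3829 in the main run. No counting interval was applied with FPKM, and the added 1 compresses the ratios of rare entries. How these set the remaining difference was not tested. Total-count scaling (6919 and 2971), median-of-ratios scaling (5643 and 3855), a pseudocount of 5 (5434 and 3542), and thinning of the normal library (5621 and 3652) left both counts within 1.5 times, as did 2 alternatives chosen after seeing the data: leaving out the 2 most abundant entries (5668 and 3829) and leaving out entries at 0 in either library (4149 and 3586). The Pearson correlation across entries was 0.783 with a minimum of 100 counts and Spearman's rho 0.834. With a minimum of 1000 counts, chosen after seeing the data and leaving 7410 entries over a narrower range of abundance, they were 0.681 and 0.682. The 4 named entries kept their direction under all 4 alternatives run for them, and 6 of those 16 log2 ratios left the counting interval. The medians of gene lists and of annotation categories, and their alternatives, were not run, because the entries have no names. No paired analysis was possible because each group held 1 library, and no library could be left out for the same reason. Depth limits statements on the entries under 20 counts, which are 71.7% of all.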

Other observations

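Among the tests reported here, those of depth, of RNA from another organism and of split alleles were chosen only after the result was seen; the others had their outcomes set down first, for patterns already noticed in these data. The test for RNA from another organism replaced an earlier one whose range of ratios left out the entries at 0, and that for a loss of reads replaced one that restated the pattern. Transcript use differed for a small number of entries. The deposited length of an entry with several transcripts differs between the libraries where they use its transcripts in different proportions. Of 5161 such entries with at least 100 counts in each library, 49 were at least 1.41-fold longer in the mutant library and 27 at least 1.41-fold shorter. Of these 76, 54 differed by less than 2-fold in count, so a comparison of counts alone does not show them. The median log2 length ratio was 0.001, and there is no replicate to give its spread.

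Entries with the first part of their identifier in common moved together to a degree. Over 893 pairs, the 2 most abundant entries of each such component with at least 100 counts, log2 ratios correlated with a Pearson r of 0.385 and a Spearman rho of 0.333, and the highest r of 1000 shuffles of the pairs was 0.11. Signs were equal in 61.8% of pairs. In 14 of the 92 pairs in which both members differed at least 2-fold, the members differed in opposite directions. Entries are not independent replicates.

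The first pattern is the larger number of entries detected in the shallower mutant library. Depth is argued against by its direction, since the normal library had more counts and detected 63036 entries against 79546. A few abundant entries taking up the normal library are argued against as well: without the 100 most abundant entries and at equal totals, the mutant library still detected 1.277 times as many. An even background of reads over all entries, such as genomic DNA would give, remains open. Of 218 entries of at least 1000 bases with 1 to 19 counts over both libraries, 3 were at 0 in the mutant library. Such a background allows 3.5, and 50 were at 0 in the normal library. The allowance was itself set from the excess counts of entries with 1 to 19 counts. Under this selection an entry at 0 in the normal library also cannot be at 0 in the mutant library. The comparison therefore does not decide. The excess was not uniform, with 2.31 counts per 1000 bases in entries of under 300 bases and 4.41 in those of 300 to under 500 bases. It was 5.47 in those of 500 to under 1000 bases and 4.74 in those of at least 1000 bases. A broader set of rare transcripts in the mutant or in its cultivar stays open, untested.

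The second pattern is the 1520 entries counted in the mutant library and at 0 in the normal library, against 243 in the opposite direction. RNA of another organism in the mutant sample may account for part of them, and would form a group apart. Among entries with at least 300 counts in the library that was higher, 132 lay at log2 ratios of 6 or more and 81 at 3 to 6 towards the mutant library, a ratio of 1.63, against 58 and 150 towards the normal library, a ratio of 0.39. Genes found in only 1 of the cultivars or catkin types would give such a group too, entries at 0 are placed by the pseudocount, and no sequences were used here to assign entries to a species, so these values do not decide. The values also cover little of the pattern: of the 1520 entries, 174 had at least 100 counts in the mutant library. Of the 132, 67 lay at log2 ratios of 6 to under 9 and had counts in the normal library as well. Alleles of the cultivars split over 2 entries would give partners at 0 in the mutant library, which existed for at most 15.99%, but an allele present in both libraries would leave no such partner, so this stays open.

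The third pattern is the shift of entries of at least 2000 bases towards the mutant library. Entries of at least 2000 bases lay 0.32 above those of 1000 to under 2000 bases. With FPKM, which uses the effective length of each library, 96.8% of this difference remained. Here log2(FPKM + 0.01) was used in place of log2(FPKM + 1). The deposited gaps between length and effective length, 77.86 and 84.37 bases, are so alike that FPKM could hardly change ratios of such long entries. The deposited effective lengths thus do not account for the difference. A length effect that they do not capture was not tested. Abundance in counts alone is argued against, since the median of the longest class lay at percentile 100 of the matched lists. Those lists were matched on counts without a correction for length. At equal counts a longer entry is rarer per base, and rarer entries leaned towards the mutant library. Abundance per base therefore stays open, and the abundance bins used below have the same limit. A loss of reads from long transcripts in the normal library, for instance through RNA of lower integrity, stays open: less the median of their abundance bin, the 453 entries of at least 4000 bases lay 0.47 above the 3330 of 2000 to under 3000 bases in median log2 ratio (95% bootstrap interval over entries 0.40 to 0.54), so the shift went on with length. Any cause that acts on length would give this, a difference between catkin types or cultivars included, and with 1 library per group these cannot be told apart.

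Among entries at least 256-fold apart with at least 2000 counts in the library that counted them, the other library held 58 counts against 94150 for the 12 entries of the mutant library, or 0.0616%, and 60 against 52734 for the 7 entries of the normal library, or 0.1138%. The 256-fold limit alone keeps both shares low, so they do not measure absence. Of the 92000 entries, 5 were at 0 in both libraries after rounding.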
